A study of Homo sapiens with 12 samples.

How the data were processed

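RNA of 12 samples of 1 cell line was hybridised to 12 one-colour Affymetrix arrays. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit, and biotinylated cRNA was made from 5 ug of it with the single-cycle 3' IVT protocol. Per the submitters' processing notes, the deposited intensity of each probe set is a MAS5 signal, and its version is not given in the sources used here. The deposited intensity values were on a linear scale and were positive, and the mean between the 2nd and 98th percentile of each array was about 1000 (999.9), so each array had been scaled to a common level before deposit. The other steps, such as background settings and image analysis, were not given in the sources used here, and detection calls were not used here. MAS5 signals of dim probe sets vary more between arrays than bright ones on the log scale, and a common scaling removes any difference in total RNA per cell.

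A table of the platform's annotation paired 41097 of the 54675 probe sets with 1 gene symbol and 1801 with several. The other 11777 were unnamed there. Of the probe sets with 1 gene, 41043 matched the RefSeq gene table of assembly GRCh38.p14 by gene number, and no symbol needed an update. That table served for names and for the order of genes along the genome alone. No gene was named from a probe set with several. For each of the 19775 genes, the probe set with the highest mean log2 signal over all 12 arrays was kept. The 62 control probe sets and genes below the 40th percentile of that mean (a signal of 65.9) were left out, which left 14266 genes. Where probe sets past the filter differed in sign for a gene that the rule below named and the report prints, this is given in the comparison concerned.

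Signals below 1 (191 values) were set to 1 before log2. A linear model with the 3 groups was fitted to all 12 arrays in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes with an intensity trend), so that the groups shared 1 estimate of the spread with 9 residual degrees of freedom. Calls used a Benjamini-Hochberg adjusted p under 0.05 within each comparison, and tests were two-sided. Fold changes are 2 to the power of the difference of mean log2 signals, and means ± SD are on the linear signal. The 21 gene lists held 516 distinct members, of which 471 had a named probe set and 444 were tested. Some members had no named probe set and are not reported here. Lists were tested with camera at a preset correlation of 0.01, adjusted over 21 lists and 3 comparisons together, with an estimated correlation and with fry as alternatives. Single array measures were compared with exact two-sided permutation tests.

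The groups, the tests of genes and gene lists, the lists, the alternatives and the rule for named genes were fixed before the data were examined. Some tests of explanations were chosen later, and this is said where they are given. The rule named CXCR4, CXCL12 and ACKR3 in every comparison. It also named the genes with an adjusted p under 0.05 and non-overlapping arrays that had the 10 highest and 10 lowest log2 fold changes (5 and 5 for the third comparison). Where fewer than 5 passed in a direction, the smallest p up to 5 were given as values that did not pass. From each called list it took up to 4 members with the smallest p, and from each other list up to 2 passing members. Alternatives covered the scaling between arrays, the constant added before log2, the filter, the variance model, the arrays in the fit, the handling of probe sets, array weights, a minimum fold and leaving out each array. The same titles give replicate numbers 1 to 4 in each group without saying that a number marks a shared day, so the model had no block, and a fit with the number as a block was an alternative. Subtracting the median of 50 neighbouring genes was added after seeing the data.

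The model was tested on simulated data, with unchanged groups drawn from the fitted spread and 200 genes changed by 1.25-fold to 4-fold. Over 20 simulations of SDF-1 against untreated cells on 14266 genes, 4.65% of calls were false, and 15.6% of genes changed 1.25-fold were recovered. The immediate-early list raised 1.25-fold was called in 20 of 20, with a mean of 0.55 other lists called per simulation. Each simulated gene varied independently of the others, so the list result may be too favourable for real genes that vary together. Some other lists share members with it, and the 200 changed genes could fall in any list, so this mean is not a rate of false calls.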

Results

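Transcript levels were measured in MDA-MB-231, a human breast cancer cell line of mesenchymal appearance that lacks the oestrogen receptor and is used as a model of metastasis. The cells had been sorted by CXCR4, the chemokine receptor that binds SDF-1 (stromal cell-derived factor 1, the product of CXCL12), and were cultured for 3 days after sorting. Each of 3 groups had 4 arrays: untreated CXCR4-negative cells, untreated CXCR4-positive cells, and CXCR4-positive cells given 400 ng/ml SDF-1alpha for 1 hour. The values were MAS5 signals of 54675 probe sets, and the median signal per array ranged from 119.2 to 159.3. Within groups, the mean Spearman correlation of an array with the other 3 lay between 0.975 and 0.981 across the 14266 tested genes, 1 probe set each. The labels do not say whether the 4 samples of a group came from separate cultures, so all p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

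CXCR4 itself separated the sorted populations on every array. Its brightest probe set had a signal of 15804 ± 1363 (SD, n = 4) in CXCR4-positive cells and 3310 ± 187 (SD, n = 4) in CXCR4-negative cells, a 4.77-fold difference (log2 fold change 2.25, SE 0.08, limma adjusted p = 1.18e-12). The other 2 probe sets of the gene gave 6.81-fold and 5.59-fold. CXCR4-negative cells kept a CXCR4 signal far above the filter for dim probe sets, which lay at 65.9. After SDF-1 the signal of the brightest probe set was 16724 ± 982 (SD, n = 4), a log2 change of 0.08 against untreated positive cells that did not pass (adjusted p = 0.910), and the other 2 probe sets gave -0.02 and -0.07. CXCL12, which encodes the ligand, had a low signal in both untreated groups, 144.5 ± 73.0 in positive and 164.4 ± 43.2 in negative cells (SD, n = 4; adjusted p = 0.667). ACKR3, the other receptor for SDF-1, had 91.3 ± 21.9 in positive and 60.5 ± 25.3 in negative cells, the latter below the filter (SD, n = 4; adjusted p = 0.459).

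**Figure D1:**
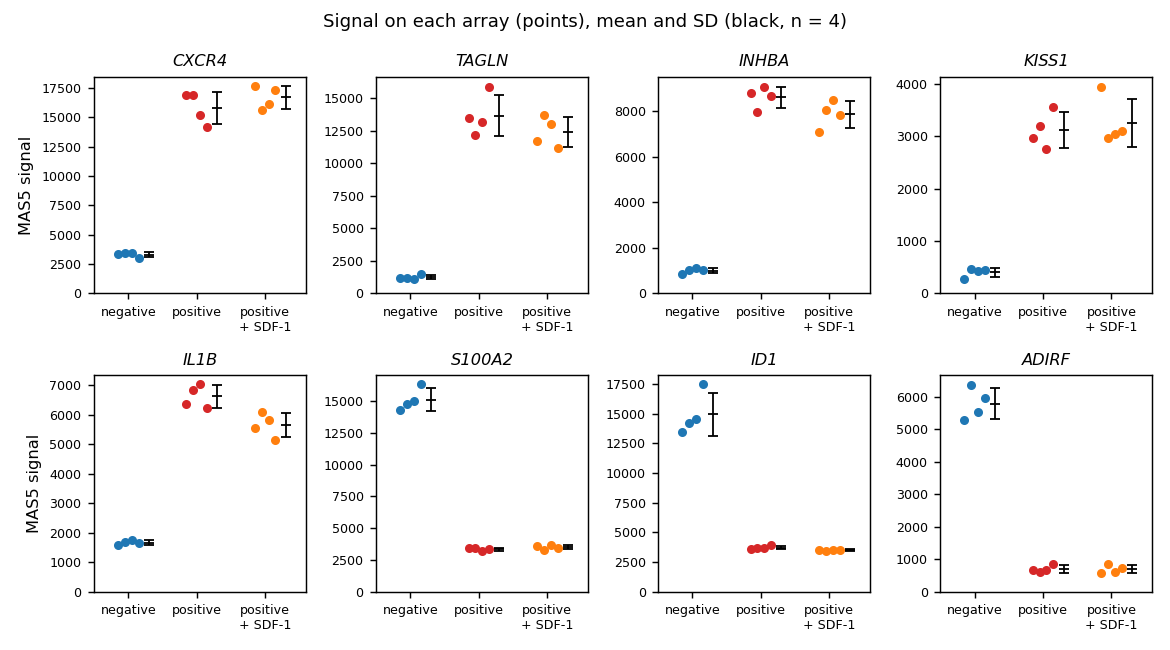
MAS5 signal (vertical axes, linear and starting at 0) of 8 genes on each of the 12 arrays, by group (points), with the group mean and SD beside them (black, n = 4). CXCR4 lies between 3032 and 3426 on the negative arrays and at 14163 or above on the positive ones, and S100A2, ID1 and ADIRF show the opposite order.

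The first comparison asked which transcripts differ between untreated cells with and without the receptor. TAGLN, the actin-binding protein transgelin, was 11.03-fold higher in CXCR4-positive cells (13653 ± 1577 against 1239 ± 150, SD, n = 4), and INHBA, which encodes the activin A subunit, was 8.65-fold higher (8608 ± 461 against 1000.5 ± 122.7, SD, n = 4). The interleukin genes IL1B and IL1A were 3.97-fold and 4.36-fold higher. These are values of the brightest probe set of each gene, and another probe set of TAGLN and of IL1A did not show such a rise, as given below. Lower in CXCR4-positive cells were S100A2, a calcium-binding protein of basal epithelium (3354 ± 113 against 15099 ± 889, 4.50-fold), and ID1, an inhibitor of basic helix-loop-helix transcription factors (3710 ± 139 against 14922 ± 1778, 4.00-fold; SD, n = 4 for each). Of 14266 genes tested, 3043 differed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 1495 of them higher and 1548 lower in CXCR4-positive cells, and 438 of the 3043 differed at least 2-fold. With array medians set equal the split was 1721 higher and 1307 lower.

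Besides TAGLN and INHBA, the 10 genes with the highest fold changes among those whose arrays did not overlap included the potassium channel gene KCNJ15 (10.2-fold), the neural adhesion gene CNTN1 (10.1-fold), the kisspeptin gene KISS1 (7.87-fold), and the kinase genes NRK (7.68-fold) and ALPK2 (7.39-fold). The non-coding transcripts LINC00839 and SLC8A1-AS1 were 12.8-fold and 10.4-fold higher, and the hair keratin gene KRT33B was 7.89-fold higher. At the other end stood TNS4, a focal adhesion protein (11.1-fold lower), HLA-DRB4, an MHC class II beta chain (10.6-fold lower), and CCL20, a chemokine (9.56-fold lower). ADIRF was 8.34-fold lower, RAB37 8.12-fold, S100P 7.31-fold, the adhesion molecule gene VCAM1 7.11-fold, the chemerin receptor gene CMKLR1 6.68-fold, IFITM10 6.36-fold and the aldehyde dehydrogenase gene ALDH3A1 5.96-fold lower. The adjusted p of these 20 genes lay between 3.46e-13 for TAGLN and INHBA and 0.0103 for IFITM10. LINC00839, KRT33B, HLA-DRB4, CCL20, VCAM1 and IFITM10 had a mean log2 signal below the filter in the dimmer group, so the size of their fold changes is uncertain, and the near-identical HLA-DRB genes can share hybridisation. ALDH3A1 was dim and variable in positive cells (96.2 ± 88.6, SD, n = 4), so the size of its fold change is uncertain too. Over all tested genes, the 4 positive and 4 negative arrays did not overlap for 23.7%, where chance gives 2.86%. A required change of 1.5-fold leaves 1123 genes, and testing every probe set on its own calls 4976 probe sets.

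**Figure D2:**
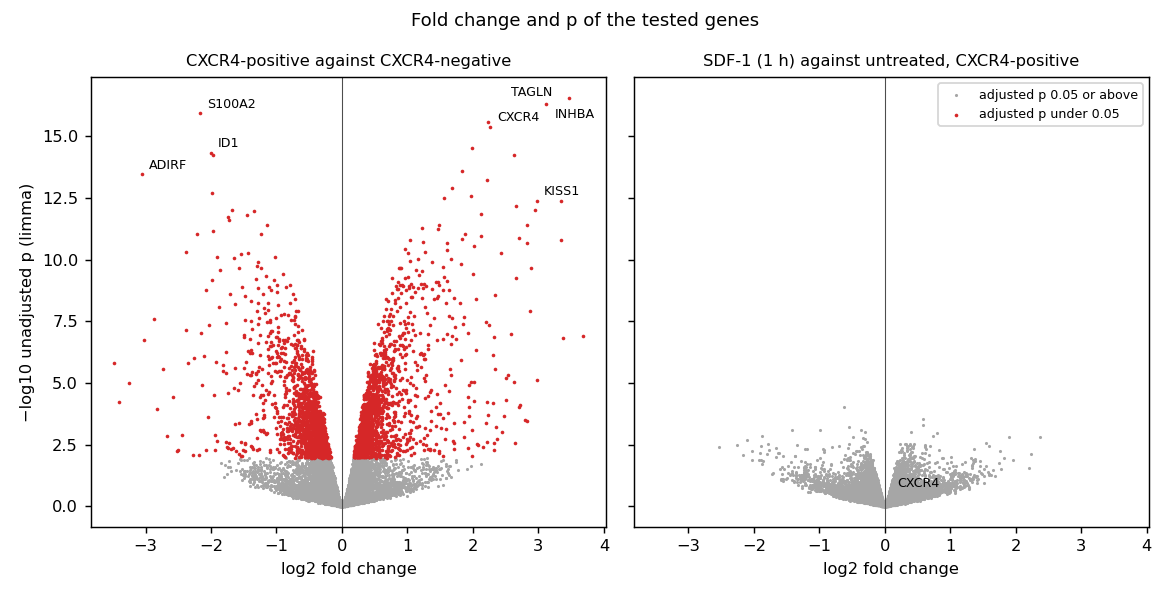
Log2 fold change (horizontal) against −log10 of the unadjusted limma p (vertical) for the 14266 tested genes, for CXCR4-positive against CXCR4-negative cells (left) and SDF-1 against untreated CXCR4-positive cells (right). Red points have an adjusted p under 0.05, 3043 on the left and 0 on the right.

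Of the 21 gene lists fixed before the data were examined, 4 were lower in CXCR4-positive cells relative to the other tested genes (camera with a preset correlation of 0.01, Benjamini-Hochberg over 63 tests), and 0 were higher. Interferon-stimulated genes had the most lower members of the 4 lists: 11 of 26 tested fell, 3 rose and 12 did not pass (adjusted p = 0.00394, adjusted p = 0.2004 with an estimated correlation). Among them BST2, which tethers virions, was 2.03-fold lower (4267 ± 143 against 8649 ± 252, SD, n = 4), IFI44 2.00-fold, OASL 1.91-fold and IFITM1 1.61-fold lower. Of the epithelial and luminal genes 7 of 23 fell and 16 did not pass (adjusted p = 0.0128, adjusted p = 0.223 with an estimated correlation), with MAL2, an apical transport protein, 5.23-fold, the trefoil factor gene TFF1 5.19-fold, the mucin gene MUC1 4.29-fold and the tight junction gene CLDN4 1.84-fold lower. Of the mitotic genes of the G2 and M phase 9 of 28 were lower and 19 did not pass (adjusted p = 0.0124, adjusted p = 0.151 with an estimated correlation), among them MKI67 (1.54-fold lower), KIF20A (1.34-fold), CKS2 (1.31-fold) and CDCA8 (1.29-fold). For MKI67, the 4 probe sets gave log2 fold changes from -0.62 to -0.01.

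Basal epithelial markers, a list of another cell type, had 6 tested members, of which 3 were lower and 3 did not pass (adjusted p = 0.00150, adjusted p = 0.0881 with an estimated correlation). The lower members were S100A2, the laminin-binding integrin gene ITGB4 (3.67-fold) and the laminin gene LAMB3 (1.21-fold), and SFN had a log2 difference of -0.20 that did not pass (adjusted p = 0.105). Adjusted over the list alone, the numbers of lower members were 11 for interferon, 7 for epithelial, 9 for mitotic and 4 for basal genes. With an estimated correlation no list passed. Other groupings of the 8 arrays gave at least 4 called lists in 5 instances, so that 6 of the 35 splits, the real one included, reached this number. Without CXCR4-negative replicate 1, 9 lists were called. The signal of the ribosomal RNA control probe sets also moved with these groups, being 1806 ± 688 on CXCR4-negative and 925 ± 116 on CXCR4-positive arrays (SD, n = 4; two-sided exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give). The 3' to 5' signal ratio of ACTB, a measure of RNA integrity, was 1.01 ± 0.05 on CXCR4-negative and 0.99 ± 0.02 on CXCR4-positive arrays (SD, n = 4; exact permutation p = 0.457).

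**Figure D3:**
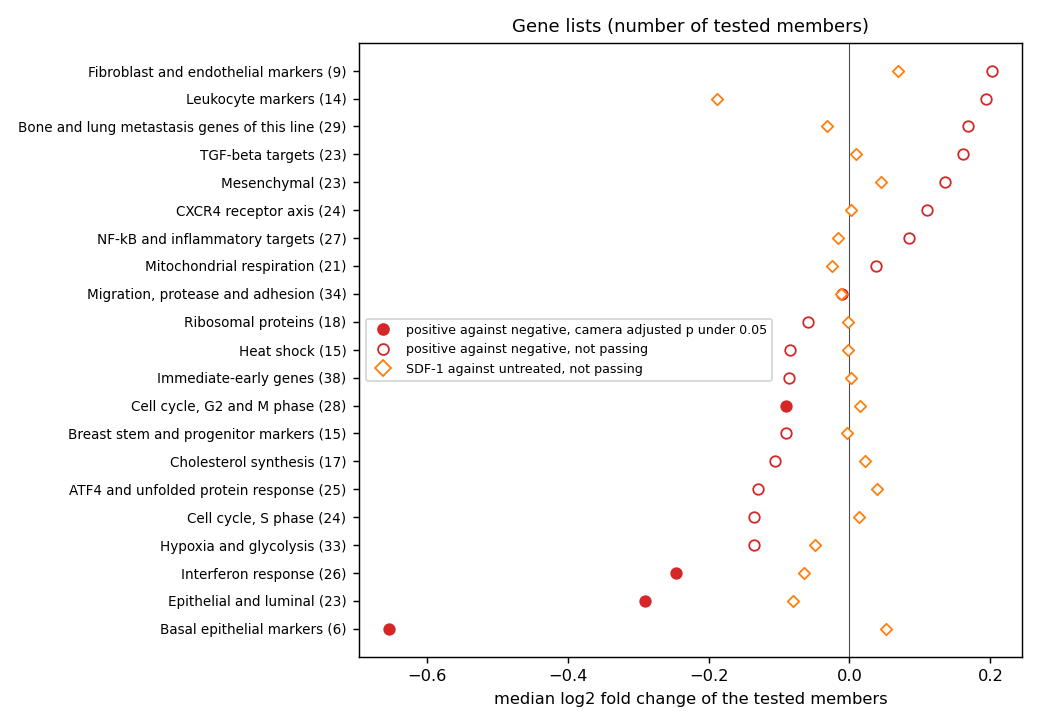
Median log2 fold change (horizontal) of the tested members of each of the 21 gene lists (vertical, number of tested members in brackets), for CXCR4-positive against CXCR4-negative cells (circles, filled where the camera adjusted p with the preset correlation is under 0.05) and for SDF-1 against untreated CXCR4-positive cells (diamonds). The 4 filled circles lie between -0.65 and -0.09, and none of the diamonds passed.

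The other 17 lists did not pass as groups, but most held members that did. In the mesenchymal list 7 of 23 tested genes were higher and 5 lower (adjusted p = 0.305), with TAGLN at one end and COL6A1 at the other (log2 fold change -1.48). S100A4, a calcium-binding protein linked to motility, was 2.74-fold lower (18548 ± 1238 against 50919 ± 4823, SD, n = 4). For TAGLN 1 of 3 probe sets had the opposite sign, with a log2 fold change of -0.21. The list of bone and lung metastasis genes of this line had 11 of 29 members higher, CXCR4 among them, and 9 lower, ID1 among them (adjusted p = 0.821). It mixes genes reported higher with genes reported lower in bone- or lung-tropic derivatives. A test for a shared direction therefore cannot show whether that pattern was present, and the rise of CXCR4 follows from the sort. NF-kB and inflammatory targets were higher in 9 of 27 and lower in 4 (adjusted p = 0.294). CCL20, below the filter in the dimmer group, was among the lower members, and IL1A and IL1B were among the higher ones, with a second IL1A probe set at a log2 fold change of 0.10. TGF-beta targets were higher in 8 of 23 and lower in 4 (adjusted p = 0.122), with THBS1, an extracellular matrix glycoprotein, 2.24-fold higher (27781 ± 1705 against 12450 ± 1613, SD, n = 4) and ID1 lower. Migration, protease and adhesion genes were split evenly, 10 of 34 higher and 10 lower (adjusted p = 0.740), with the integrin gene ITGB3 3.21-fold higher and ITGB4 lower. For ITGB3, probe sets past the filter ranged from -0.11 to 2.08 on the log2 scale. In the CXCR4 receptor axis 5 of 24 were higher and 3 lower (adjusted p = 0.148). The higher members included CXCR4 itself, whose rise follows from the sort and enters the test, and the G-protein regulator gene RGS4, 4.36-fold higher.

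Among stress and metabolic lists, hypoxia and glycolysis genes were lower in 12 of 33 and higher in 5 (adjusted p = 0.0624), with DDIT4 2.42-fold and the carbonic anhydrase gene CA12 2.19-fold lower. Of the 6 probe sets of CA12 past the filter, the log2 fold changes ranged from -1.30 to 0.11. Heat shock genes were lower in 5 of 15 and higher in 0 (adjusted p = 0.0624), with the small chaperone gene HSPB1 1.61-fold and HSPA4L 1.57-fold lower. The ATF4 and unfolded protein response list had 4 of 25 lower and 0 higher (adjusted p = 0.122), with the asparagine synthetase gene ASNS 1.61-fold and MANF 1.22-fold lower. Immediate-early genes were lower in 9 of 38 and higher in 7 (adjusted p = 0.129), with ID1 and KLF4 (2.05-fold) lower. S phase genes were lower in 7 of 24 and higher in 2 (adjusted p = 0.125), with MCM7 1.40-fold and UHRF1 1.39-fold lower. Cholesterol synthesis genes were lower in 3 of 17 and higher in 2 (adjusted p = 0.443), with INSIG1 1.53-fold and MSMO1 1.36-fold lower.

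Breast stem and progenitor markers were higher in 4 of 15 and lower in 2 (adjusted p = 0.903), with the aldehyde dehydrogenase gene ALDH1A3 2.77-fold higher (1361 ± 221 against 488 ± 34, SD, n = 4) and KLF4 lower. Leukocyte markers were higher in 2 of 14 and lower in 2 (adjusted p = 0.903): the actin-bundling gene LCP1 was 4.64-fold higher and LAPTM5 2.20-fold lower. Fibroblast and endothelial markers were higher in 2 of 9 and lower in 1 (adjusted p = 0.903), TIE1 being 2.83-fold higher and PECAM1 2.44-fold lower. Of the ribosomal protein genes 1 of 18 was lower, RPS23 by 1.19-fold (adjusted p = 0.482 for the list). Of the respiratory chain genes 1 of 21 was higher and 2 were lower (adjusted p = 0.943), COX5B being 1.22-fold higher and COX7C 1.18-fold lower. For COX5B the sign turned when the median of neighbouring genes was subtracted (log2 difference -0.06). Test direction and mean differed in sign for the NF-kB and the metastasis lists, where the test pointed up, the medians were 0.08 and 0.17 and the means -0.0019 and -0.07.

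The second comparison asked which transcripts changed within 1 hour of SDF-1 in cells that carry the receptor. No gene passed: limma called 0 of 14266 genes, the smallest adjusted p was 0.894, and 711 genes (4.98%) had an unadjusted p under 0.05. Without SDF-1 replicate 2, the array with the lowest correlation with its group, 1106 genes had an unadjusted p under 0.05 and 0 were called. The 95% confidence interval excluded a 2-fold change in either direction for 11001 genes (77.1%), and a 1.5-fold change for 62.4%. Immediate-early genes, transcripts that many receptors induce within this time, had 0 of 38 members higher and 0 lower, both over all genes tested and adjusted over the list alone, with a median log2 fold change of 0.0021. For 37 of them the upper 95% bound lay below a 2-fold rise and for 34 below a 1.5-fold rise.

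Values that did not pass illustrate the size of the differences. Of the 38 immediate-early genes tested (42 were on the list) 6 had an unadjusted p under 0.05, all with an adjusted p of 0.894. This is a larger share than the 4.98% over all tested genes. The log2 differences were 0.53 for ZFP36, 0.27 for EGR1, 0.22 for SRF and 0.17 for DUSP5 toward higher values, and -0.32 for GEM and -0.18 for SPRY2 toward lower. ZFP36, which encodes an RNA-binding protein, had a signal of 530 ± 96 after SDF-1 and 374 ± 103 without it (SD, n = 4; upper 95% bound 1.93-fold), and GEM, a small GTPase gene with the smallest unadjusted p of the list (0.00369), had 2610 ± 124 and 3289 ± 475 (SD, n = 4). This count was chosen after the values were seen. By the rule for named genes, the smallest unadjusted p toward higher values belonged to RRS1 (1.49-fold), PRRC2B (1.503-fold), R3HDM2 (1.32-fold), CAMKK1 (1.75-fold) and UBBP2 (1.66-fold). Toward lower values they belonged to TTC38 (1.53-fold), FHIP2B (1.46-fold), SPINT1 (2.67-fold), PIDD1 (1.98-fold) and RPE (1.29-fold). All 10 had an adjusted p of 0.894, and other probe sets of PIDD1 and RPE reached log2 changes of 0.04 and 0.03, of the opposite sign. None of the 21 lists passed, the smallest adjusted p being 0.208 for hypoxia and glycolysis, with camera at an estimated correlation and with fry giving 0 lists too. Test direction, median and mean differed in sign for 8 lists here, the CXCR4 receptor axis, cholesterol synthesis, stem and progenitor, metastasis, heat shock, migration, ribosomal protein and basal lists. After quantile normalization the ribosomal protein list passed, as it did without SDF-1 replicate 4. In 20 simulations with known changes in this comparison, 70.7% of genes changed 2-fold, 49.5% of genes changed 1.5-fold and 15.6% of genes given the smallest simulated change were recovered. Among the 7003 genes with a mean signal of at least 1024 these shares were 99.6%, 89.2% and 28.9%. All these shares hold for many genes changed together, which makes the adjusted p of each easier to pass. A response of few genes would face a stricter limit and was not simulated, so the shares do not apply to it.

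The third comparison set SDF-1-treated CXCR4-positive cells against untreated CXCR4-negative cells and shares its arrays with the other 2 comparisons. Of 14266 genes 2902 differed (limma, adjusted p under 0.05), 1396 of them higher and 1506 lower in the treated positive cells. With array medians set equal the split was 1526 higher and 1278 lower. SLC8A1-AS1 was 11.7-fold, KCNJ15 10.5-fold, TAGLN 10.0-fold, CNTN1 8.81-fold and TMLHE 8.59-fold higher, with 1 of 3 TAGLN probe sets of the opposite sign (log2 fold change -0.59). HLA-DRB4 was 10.9-fold, CMKLR1 9.79-fold, CCL20 9.72-fold, RAB37 9.32-fold and ADIRF 8.46-fold lower. TMLHE, HLA-DRB4 and CCL20 had a mean log2 signal below the filter in the dimmer group. CXCR4 was 5.05-fold higher, while CXCL12 (adjusted p = 0.985) and ACKR3 (adjusted p = 0.753) did not pass. CD74, the MHC class II invariant chain, was 3.30-fold lower (2366 ± 313 against 7751 ± 322, SD, n = 4). A required change of 1.5-fold leaves 1081 genes.

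Between this comparison and the first, 1153 genes were higher in both, 1145 were lower in both and 0 were called in opposite directions. Independent lists of these sizes would share 146.3 higher and 163.4 lower genes. In 100 simulations all groups were drawn as unchanged, with the simulated negative arrays common to both comparisons. The simulated comparisons shared at most 1 gene, which follows largely from the absence of any change. Both real comparisons set CXCR4-positive cells against the same negative arrays, so neither value is a reference that the overlap could have matched. With the 4 negative arrays split between the comparisons, the 6 ways of splitting gave 669 to 722 shared higher and 588 to 645 shared lower genes.

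Gene lists called in the third comparison were 5, all lower in the treated positive cells. Interferon genes were lower in 13 of 26 and higher in 2 (adjusted p = 0.000315, adjusted p = 0.143 with an estimated correlation), with IFI44 1.94-fold, OASL 1.86-fold, BST2 1.74-fold and IFITM1 1.69-fold lower. Basal markers were lower in 4 of 6 (adjusted p = 0.00150, adjusted p = 0.0881 with an estimated correlation), namely S100A2 (4.31-fold), TRIM29 (4.40-fold), ITGB4 (3.62-fold) and LAMB3 (1.17-fold). Epithelial and luminal genes were lower in 7 of 23 (adjusted p = 0.00258, adjusted p = 0.151 with an estimated correlation), led by TFF1 (7.40-fold), MAL2 (5.67-fold), MUC1 (5.01-fold) and KRT7 (1.44-fold). Mitotic genes were lower in 8 of 28 (adjusted p = 0.0128, adjusted p = 0.151 with an estimated correlation), with CENPE 1.44-fold and CKS2 1.30-fold lower. Hypoxia and glycolysis genes were lower in 13 of 33 and higher in 5 (adjusted p = 0.0128, adjusted p = 0.311 with an estimated correlation), with DDIT4 2.53-fold, CA12 2.22-fold and NDRG1 1.96-fold lower and the collagen-modifying enzyme gene PLOD2 1.58-fold higher. This list had a camera adjusted p of 0.0624 between the untreated groups and 0.208 for SDF-1 against untreated positive cells. Its call here therefore does not show an effect of SDF-1. Adjusted over the list alone, the numbers of lower members were 14, 4, 8, 8 and 14 in the order given. Here 5 of the 35 splits of the 8 arrays gave at least 5 called lists, the real one included, and leaving out CXCR4-negative replicate 1 gave 8. Of the 16 lists not called, the NF-kB, stem and progenitor, metastasis and leukocyte lists had a test direction, median and mean that differed in sign. The ribosomal RNA control signal was 789 ± 141 (SD, n = 4) on the SDF-1 arrays and 1806 ± 688 on the CXCR4-negative ones (exact permutation p = 0.0286, the smallest possible).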

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

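The gap of an extreme array to its nearest neighbour, divided by the range of its group of 4, passed Dixon's limit in 16 of 276 groups of 4 examined over 86 named genes and 6 array measures, where chance gives about 13.8. No technical explanation was weighed for these. On CXCR4-negative arrays, CXCR4 was lowest on replicate 4 (3032, the others 3364 to 3426), S100P lowest on replicate 1 (1037, the others 1304 to 1341), HSPB1 highest on replicate 4 (17565, the others 14293 to 14503), ITGB4 highest on replicate 1 (1915, the others 1264 to 1323), SPINT1 highest on replicate 3 (379.9, the others 286.6 to 296.6) and ACAT2 highest on replicate 4 (6858, the others 5704 to 5881). Among CXCR4-positive untreated arrays, RGS4 was highest on replicate 3 (3275, the others 2828 to 2837), HSPB1 lowest on replicate 3 (8333, the others 9641 to 9922), LCP1 lowest on replicate 1 (8014, the others 8960 to 9105) and CAMKK1 lowest on replicate 3 (175.6, the others 247.2 to 262.4). With SDF-1, KISS1 was highest on replicate 1 (3948, the others 2962 to 3097), CDCA8 highest on replicate 2 (7067, the others 5654 to 5842), MAL2 lowest on replicate 2 (397.2, the others 609.4 to 653.5), RRS1 highest on replicate 4 (5592, the others 3753 to 4015) and FHIP2B lowest on replicate 3 (410.4, the others 500.7 to 519.4). The mean correlation of an array with its group was lowest on SDF-1 replicate 2 (0.975, the others 0.980).

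Control probe sets for ribosomal RNA, which the gene comparisons leave out, had 1.95 times as high a signal on CXCR4-negative as on CXCR4-positive untreated arrays, with CXCR4-negative replicate 1 the highest at 2809.

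Regrouping the 8 arrays of a comparison, with the third group held, bears on whether chance can be excluded. The 3043 genes called between CXCR4-positive and CXCR4-negative cells were reached by 1 of 35 splits, the real one, and the highest other split called 1. For SDF-1-treated positive against negative cells 1 of 35 splits reached 2902 genes, and the highest other called 0. For the number of called lists the splits leave chance open in these 2 comparisons. In the first comparison 6 of 35 splits gave at least the observed 4 lists (highest other 9), and in the third 5 of 35 gave at least the observed 5 (highest other 8). Each other split that reached these numbers had exchanged only 1 array between the groups. Such splits still carry part of the real difference, so they are no clean reference for chance. No split that exchanged 2 arrays reached the observed numbers. For SDF-1 against untreated positive cells the splits decide nothing, since a count of 0 is reached by all 35 of 35 whatever the data: 0 genes (highest other 2) and 0 lists (highest other 5).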

How the results depend on the processing

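Subtracting neighbouring genes was the 1 alternative chosen after seeing the data. Values for the CXCR4 log2 fold change between sorted populations, for 0 genes after SDF-1, and for both counts against CXCR4-negative cells stayed within 1.5 times of their values in the other alternatives run, with these exceptions. Testing every probe set on its own called 4976 in the first and 4593 in the third comparison, as more features were tested, and a required 1.5-fold change left 1123 and 1081 genes and an overlap of 832. After subtracting neighbouring genes the overlap was 1458, with 2144 and 1951 genes called, and the split of the first comparison moved from 1495 higher and 1548 lower to 1212 and 932 (1721 and 1307 with array medians set equal). In the third comparison it moved from 1396 higher and 1506 lower to 1036 and 915 (1526 and 1278 with array medians set equal). The number of called lists in the first comparison became 0 with an estimated correlation, 12 with fry, which does not compare a list with other genes, and 10 without a filter. For SDF-1-treated against negative cells it became 0 and 12. For SDF-1 against untreated cells 1 list, ribosomal proteins, was called after quantile normalization. The cause was not tested for these lists.

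Leaving out 1 array in turn gave 2523 to 3143 genes in the first comparison, 0 to 0 after SDF-1 (with 523 to 1106 genes at an unadjusted p under 0.05, 1106 without SDF-1 replicate 2), 2348 to 2924 in the third comparison, an overlap of 1917 to 2175 and a CXCR4 log2 fold change of 2.21 to 2.30. It gave 4 to 9 lists in the first comparison (9 without CXCR4-negative replicate 1), 0 to 1 after SDF-1 (1 without SDF-1 replicate 4) and 5 to 8 in the third comparison (8 without CXCR4-negative replicate 1). With the replicate number as a block 3114, 0 and 2926 genes were called. Same-numbered arrays of different groups deviated with correlations from -0.04 to 0.20, 1 of 12 pairs exceeded 0.1, and 3 of 12 arrays correlated best with their own number, so the numbers were not taken to pair the arrays.

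Signs turned for differences near 0. CXCR4 after SDF-1 was -0.0034 on the log2 scale with the mean of its probe sets. CXCL12 in the third comparison was -0.0126 with array weights, -0.104 with neighbouring genes subtracted and -0.102 to 0.18 in the fits without 1 array (below 0 at -0.0828, -0.0107, -0.0307 and -0.102). COX5B was -0.0615 in the first and -0.0965 in the third comparison with neighbouring genes subtracted. Of the named genes, 50 of 65 in the first, 12 of 13 in the second and 40 of 56 in the third comparison kept direction and call in every alternative. Among the others 38, 0 and 54 values lost the call and 1, 0 and 0 gained it. Dim signal limits the SDF-1 comparison: of 7263 genes with a mean signal under 1024, the 95% interval excluded a 2-fold change for 4003.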

Other observations

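Gene families were examined after the main comparison had been seen, and some members (among them TFF1, ID1, S100A2, S100A4, ALDH1A3, KRT7, CD74, IL1A and IL1B) also belong to the fixed lists. MHC class II genes and their chaperones were lower in untreated CXCR4-positive than CXCR4-negative cells for 8 of 15 tested members and higher for 0 (limma adjusted p under 0.05). HLA-DRA fell from 10726 ± 934 in negative to 2748 ± 154 in positive cells (SD, n = 4; 4 of 4 arrays lower, adjusted p = 9.49e-12), with log2 fold changes of -1.98 for HLA-DRB1, -1.97 for HLA-DPA1 and -1.74 for CD74. CIITA, the master regulator of the class, had a low signal in both groups and did not pass (log2 fold change 0.12, adjusted p = 0.920). Among the trefoil factors, secreted mucosal peptides, TFF1, TFF2 and TFF3 were all lower, with log2 fold changes of -2.38, -2.26 and -2.03. Of 4 ID genes, ID1 and ID3 were lower (-2.00 and -1.87 on the log2 scale), while ID2 (0.54, adjusted p = 0.0725) and ID4 (-0.64, adjusted p = 0.101) did not pass.

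S100 genes were lower for 6 of 13 tested members and higher for 0, from S100P (log2 fold change -2.87) to S100A10 (-0.56). Collagen genes went both ways, 4 of 30 higher and 4 lower: COL6A3 (1.41), COL4A1 (1.11), COL8A1 (1.03) and COL12A1 (0.50) were higher, and COL6A1 (-1.48), COL18A1 (-0.89), COL13A1 (-0.68) and COL6A2 (-0.53) lower on the log2 scale. Of 13 aldehyde dehydrogenase genes 4 were higher, ALDH1A3 (1.47), ALDH5A1 (1.31), ALDH1B1 (0.44) and ALDH6A1 (0.39), and 2 lower, ALDH3A1 (-2.57) and ALDH3A2 (-0.43). The size of the ALDH3A1 difference is uncertain, as its signal was dim and variable in positive cells. Keratin genes past the test numbered 1 higher and 4 lower of 19, the latter KRT80, KRT7, KRT8 and KRT18, and of 5 interleukin 1 genes IL1A and IL1B were higher.

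The tests of copy number, of single arrays and of the spread below were chosen after the results were seen, and those of differences between arrays, of signal, length and density, and of immediate-early genes before. Neighbouring genes shifted together between CXCR4-positive and CXCR4-negative cells. The 10340 tested genes with a mean signal of at least 256 were divided along the genome (gene order of assembly GRCh38.p14) into 196 runs of about 50, and the SD of the run medians was 0.152 on the log2 scale, where 1000 random gene orders reached at most 0.0575. In 12 runs the median was at least 0.2 higher and in 23 at least 0.2 lower. From DUSP22 to RNF182 48 of 50 genes were higher in CXCR4-positive cells (median 0.42, 32 called higher and 1 lower), and from PLPP2 to OAZ1 1 of 50 was (median -0.38, 24 called lower). The 35 shifted runs held 1850 of the 10340 genes and 831 of the 2884 called ones, and differences between all 196 runs made up 15.4% of the variance between genes. These 35 runs were picked by their medians in this same comparison, so an excess of called genes in them follows from the choice.

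Differences between arrays unrelated to the sorted population would spread run medians as widely between SDF-1-treated and untreated positive cells, but the SD there was 0.136 of that between positive and negative cells. Both groups in this check were CXCR4-positive, so it cannot see a technical difference between the negative arrays and all positive ones. The ribosomal RNA control signal differed in this way, with means of 1806 on negative, 925 on untreated positive and 789 on SDF-1 arrays. Such a difference therefore stays open for the shifted runs. Signal level, gene length and gene density explained 13.3% of the variance of run medians, and the residual SD (0.141) stayed above every random order. A different copy number of large chromosome regions in the sorted populations may account for the pattern. Large regions would span several runs, and the medians of adjacent runs correlated at 0.751 (highest random order 0.244). This remains a hypothesis from expression alone, since regulation of whole regions would look alike and no DNA was analysed here.

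For SDF-1, the tables bear on why 0 genes were called. A spread too large to see a 2-fold change is argued against for genes with a mean signal of at least 1024, where 99.9% of the 95% intervals exclude such a change. It could apply to dimmer genes, where 55.1% do. These intervals were not adjusted for the number of genes, while the calls were. They therefore do not show that a 2-fold change of a lone gene would have been called. A single array standing apart stays open: of the 8 fits without 1 treated or untreated positive array none called a gene, but the highest number of genes with an unadjusted p under 0.05 was 1106 (without SDF-1 replicate 2), against 711 with all arrays, and 4 lists in place of 0 had an unadjusted p under 0.05. A rise of immediate-early genes of at least 2-fold at 1 hour is argued against by the 97.4% of them whose upper 95% bound lies below it, EGR3 (upper bound 3.36-fold) being the exception. The immediate-early list raised by the smallest simulated change was called in 20 of 20 simulations. The real list was not called (camera adjusted p = 0.903) and had a median log2 fold change of 0.0021. The simulated genes varied independently of each other, so 20 of 20 may overstate how often real genes that vary together would be called. The median of the real list argues against a rise of that size shared by the list. Smaller changes of single genes stay open where their 95% intervals allow them. Earlier or later responses, and whether the ligand was active, stay open and were not tested.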
